A study of Mus musculus with 20 samples.

How the data were processed

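RNA recovered by immunoprecipitation with recombinant IRP2, and from control reactions without the protein, was measured on 20 Affymetrix Mouse Genome 430 2.0 arrays. Per the labels' protocols, total RNA of each tissue was pooled over several C57BL6/J mice, 4 for duodenum, liver and spleen and 6 for bone marrow and brain. Each reaction took 50 µg of pooled RNA and His-tagged IRP2 made in E. coli, the complexes were recovered with an antibody against the tag, and a control reaction without IRP2 ran in parallel. About 120 ng of the recovered RNA went through a two-cycle amplification and biotin labelling, per the labels' protocols. The mice of the first 3 tissues ate a diet with less than 10 mg iron per kg for 21 days from weaning, and those of the other tissues were 8 to 10 weeks old on an iron-normal diet.

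The deposited values are log2 probe set summaries, which the authors made by background correction, normalization between arrays and summarisation, per the series' design text, before they were deposited. That text names RMA in Bioconductor or MAS5 in GCOS with quantile normalization, without versions, and the values lie between 1.77 and 15.0 on a log2 scale. The array medians fell in separate ranges, 5.65 to 5.71 for duodenum, liver and brain replicate 1 and 5.39 to 5.55 for spleen, bone marrow and brain replicate 2, so the arrays were probably not normalized in 1 run. Contrasts were therefore taken within tissues, where IRP2 and control arrays of 1 replicate number lie in the same range. The leading fit described below does not pair arrays by replicate number. In brain, the difference between the ranges therefore entered its spread. Because that spread is pooled over tissues, this adds to the SEs of every tissue.

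Of 45101 probe sets, 64 Affymetrix controls were set aside, and 30153 (66.9%) were tested because their value reached the median of their own array on at least 2 of the 20 arrays. Gene symbols came from the platform annotation, and 34958 probe sets had 1 symbol, 932 several and 9211 none. Of those with 1 symbol, 34754 had a gene ID in the RefSeq table and 204 did not, and no symbol was changed. The 25133 tested probe sets with 1 symbol belonged to 14872 genes. Probe sets with several symbols or none were tested and counted but are not named.

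The values were fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 10 groups of tissue and reaction. The contrasts were IRP2 reaction minus control reaction in each tissue, their mean over the 5 tissues, and a moderated F test that the tissue contrasts are equal. P-values were adjusted by Benjamini-Hochberg over the probe sets tested in each contrast, and an adjusted p under 0.05 was a call. The fit left 10 residual degrees of freedom and a prior of 5.34. The arrays give no read depth, and the precision is the spread between 2 arrays per group, pooled over groups.

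The labels number the replicates and say that the control ran in parallel. Arrays with the same number were checked for shared deviations from their group means: these correlated across probe sets at 0.676 in duodenum, 0.565 in liver, 0.385 in spleen, 0.251 in bone marrow and 0.923 in brain. The numbers were therefore treated as pairs, a pairing that comes from these values, and a second fit used tissue and replicate number as a block (5 residual degrees of freedom, prior 7.52). The fit without the block had been fixed as the leading one before the data were examined, as were the groups, contrasts, gene lists, rule for named genes and most alternatives.

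Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes. Each gene entered by its probe set with the highest mean, and p-values were adjusted over 18 lists in 6 comparisons, 108 tests. The lists were IRE mRNAs, other mRNAs reported as bound by an IRP, and iron metabolism without a canonical IRE. Further lists were heme synthesis, citrate cycle, respiratory chain, cytosolic ribosomal proteins, replication-dependent histones, immediate early genes and housekeeping genes. The rest were markers of duodenal epithelium, liver, spleen B and T cells, bone marrow myeloid cells, brain, erythroid cells, pancreas acinar cells and muscle. Members were also counted after adjustment over the list alone.

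The rule for named genes took, in each comparison, every measured IRE mRNA on its brightest probe set, the 10 highest and 5 lowest called genes whose 2 IRP2 arrays lay on the same side of both controls (in every tissue for the mean), up to 4 members of each list described, and the 10 genes with the smallest p for the tissue difference. Genes outside it are said to be chosen after their values were seen.

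The fits were tested on simulated data with 200 of 30153 probe sets changed. The simulated noise had the same spread in every tissue, in equal parts for the pair and the array. Tissues therefore differ only by the draw. In the real data the log2 ratios of bone marrow pair 1 had an SD of 0.568, against 0.214 to 0.277 in the other tissues, and the correlation within pairs also varied. The percentages that follow thus do not measure recovery in bone marrow or any other single tissue. At 4-fold, limma recovered 92% in duodenum, 89% in liver, 91% in spleen, 90% in bone marrow and 89% in brain. At 2-fold it recovered 3%, 1.5%, 1.5%, 5% and 6.5%, and with the replicate block 15%, 26.5%, 18.5%, 27.5% and 21%. On the mean over tissues it recovered 87.5% at 2-fold, or 98.5% with the block.

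Alternatives were no filter, a filter at the 75th percentile, quantile normalization over all arrays, median centring, a trended and robust prior, array weights, the replicate block, an adjusted p under 0.01, a 2-fold minimum, a fit of each tissue alone, tissues as replicates, leaving out each array in turn, and for lists an estimated correlation and the mean of all probe sets. Fits without the bone marrow arrays, or without bone marrow and brain, were added after the data were seen. A planned offset for linear values did not apply, and a planned search for IRE motifs was not run because no transcript sequences were used here.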

Results

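Iron regulatory protein 2 (IRP2) is a cytoplasmic RNA-binding protein that recognises iron-responsive elements (IREs), stem-loops in the untranslated regions of mRNAs of iron metabolism. The series asked which mRNAs of mouse tissues IRP2 binds. Total RNA from duodenum, liver, spleen, bone marrow and brain of C57BL6/J mice was mixed with recombinant IRP2 carrying a His tag, the complexes were recovered with an antibody against the tag, and a control reaction left the protein out. The recovered RNA was amplified and hybridised to 20 Affymetrix Mouse Genome 430 2.0 arrays, 2 per tissue and reaction, which makes 10 groups. Duodenum, liver and spleen came from mice on an iron-poor diet for 21 days from weaning, and bone marrow and brain from mice of 8 to 10 weeks on an iron-normal diet. Between these sets of tissues, diet and age therefore cannot be told apart from tissue. Tissues within a set share the diet and, as far as the labels give it, the age. Per the labels, RNA samples were pooled per tissue before the reactions; whether both replicates drew on the same pool is not given in the sources used here, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. Of 45101 probe sets, 30153 passed the filter on dim signals and were tested. Values below are log2 ratios of the IRP2 reaction to the control reaction with their standard errors (SE), and a probe set was called where limma's adjusted p was under 0.05. Replicates with the same number varied together. A limma fit with replicate number as a block is given where it changed a call or moved a count by more than 1.5 times. At an unadjusted p under 0.05, chance gives 1508 probe sets in both directions together. Limma without the block gave 316 higher and 64 lower in duodenum, 166 and 47 in brain, and 583 and 283 on the mean over tissues. Liver and spleen also lay below chance. That fit was thus too conservative there, and a probe set not called may still differ between the reactions.

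Averaged over the 5 tissues, the highest ratio was that of Tfrc, the transferrin receptor that carries iron into cells, at 3.30 ± 0.19 (SE, n = 10 arrays per reaction), a fold of 9.87. Next among probe sets with 1 gene symbol came Cxcl16, a membrane-bound chemokine, at 2.52 ± 0.12. Lrpap1, a chaperone of the LDL receptor family, followed at 2.26 ± 0.13, and Nt5c, a cytosolic nucleotidase, at 1.95 ± 0.14. The iron exporter Slc40a1 (ferroportin) stood at 1.61 ± 0.11 and the iron importer Slc11a2 at 1.45 ± 0.12. The rule for named genes takes the 10 highest with both IRP2 arrays above both controls in all 5 tissues, and the remaining ones were Fam98b at 1.60, Ralgapa1, a subunit of a GTPase-activating complex for Ral, at 1.56, the ETS transcription factor Erg at 1.44 and Arfip2, which binds Arf-family GTPases, at 1.41. Their adjusted p-values ran from 3.1e-08 for Cxcl16 to 0.000656 for Erg. Several of these genes have other probe sets near 0 on the mean: the brightest of Lrpap1 had -0.02, that of Ralgapa1 0.24 and that of Erg 0.12, and the dimmer one of Arfip2 0.01. The control level of the enriched Erg probe set lay below the 10th percentile of the tested probe sets in liver (4.68 against 4.82) and brain (3.63 against 4.86). The size and rank of its mean ratio are therefore uncertain. Egr2 (1.69 and 1.62 on its probe sets) and Kcnf1 (1.59, and 0.05 on its brighter probe set) were also called. They did not have both IRP2 arrays above both controls in all 5 tissues, and both are named here after their values were seen. Altogether 110 probe sets of 72 genes were higher with IRP2, 22 of the probe sets having no single gene symbol, and 51 of the 110 were at least 2-fold higher. Only 2 were lower: Marveld1 at -0.93 (adjusted p = 0.00317) and Blmh, which encodes bleomycin hydrolase, at -0.76 (adjusted p = 0.00156). Both fall outside the rule for named genes and were chosen after their values were seen, and their other probe sets had -0.07 for Blmh and from -0.05 to 0.06 for the 3 of Marveld1. With replicate number as a block, 322 probe sets were higher and 44 lower, and the 110 were all kept. Without bone marrow control replicate 2 the count lower was 15.

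Among the mRNAs with a textbook IRE, 6 of the 8 listed before the data were examined were measured by a probe set with 1 gene symbol. The test of the list as a whole (camera, adjusted over 108 list tests) gave an increase with IRP2 on the mean over tissues, with a median of 1.14 over the 6 genes (adjusted p = 7.1e-44, and adjusted p = 2.4e-05 with an estimated correlation). On each gene's brightest probe set, Tfrc stood at 1.90 ± 0.12, Alas2, which encodes the first enzyme of heme synthesis in red cell precursors, at 1.52 ± 0.11, Slc11a2 at 1.45 ± 0.12 and Fth1, the ferritin heavy chain, at 0.83 ± 0.09 (SE, n = 10 per reaction). These 4 were called over all probe sets, and 6 when adjusted over the list alone. For the other members, Epas1, which encodes the hypoxia-inducible factor HIF-2α, had 0.46 ± 0.14 (adjusted p = 0.576) and the brightest Slc40a1 probe set 0.45 ± 0.12 (adjusted p = 0.356). Both were called with the replicate block (adjusted p = 0.0112 and 0.0303). The dimmer Epas1 probe set was called without it, at 0.77 (adjusted p = 0.00688), and with the block also in duodenum, liver and spleen (adjusted p = 0.022, 0.0102 and 0.0226).

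**Figure D1:**
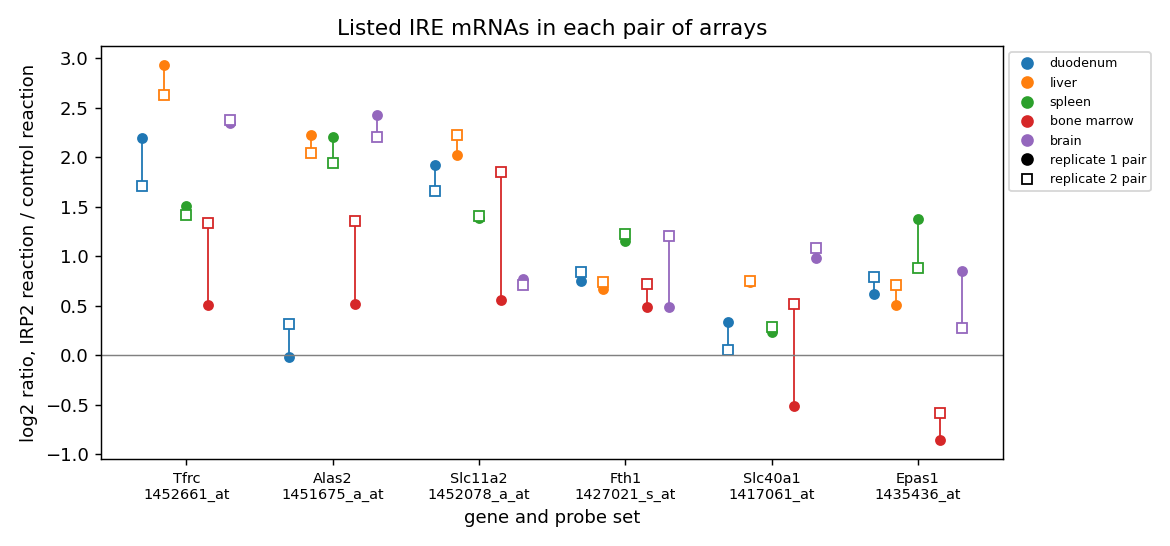
Log2 ratio of the IRP2 reaction to the control reaction (vertical axis) for the brightest probe set of 6 listed IRE mRNAs (horizontal axis); each colour is a tissue, filled circles are the replicate 1 pair, open squares the replicate 2 pair, and a line joins both pairs. Tfrc lies above 0 in every pair, with tissue means from 0.92 in bone marrow to 2.78 in liver, and Epas1 lies below 0 in both bone marrow pairs, with a mean of -0.72 on this probe set and 0.10 on its dimmer one.

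In duodenum, the absorptive part of the small intestine, Tfrc again had the highest ratio, at 3.61 ± 0.43 (SE, n = 2 per reaction), a fold of 12.2, and the next named gene was Cxcl16 at 3.23 ± 0.27. Kcnf1, a modulatory potassium channel subunit, reached 2.67 ± 0.34 from a control level of 3.72, below the 10th percentile of the tested probe sets (4.88), so the size of this ratio is uncertain, and Ppp1r1b, the phosphatase inhibitor DARPP-32, reached 2.58 ± 0.43. The glutathione transferase gene Gstm6 (2.52), Lrpap1 (2.47), Nt5c (2.20), Shisa2 (2.01), Hmces, which encodes a sensor of abasic sites in DNA (1.89), and the deubiquitinase gene Bap1 (1.82) completed the 10 highest named genes, with adjusted p-values from 9.87e-05 to 0.0354. The brightest probe sets of Kcnf1 and Lrpap1 had -0.01 and 0.31. Of the IRE mRNAs, Tfrc (1.95) and Slc11a2 (1.79 ± 0.28), the transporter of dietary iron in this tissue, were called on their brightest probe sets, and 3 were called when adjusted over the list alone. Alas2 had 0.15 ± 0.26 (adjusted p = 1.0). The list was higher as a whole (camera, adjusted p = 2.46e-16, or 0.00107 with an estimated correlation). In all, 22 probe sets of 16 genes were higher and 0 lower by limma, with 316 and 64 at an unadjusted p under 0.05. The replicate block gave 85 higher and 4 lower, and the named genes among the 4, chosen after their values were seen, were Marveld1 (-1.21), Blmh (-0.98) and Snrpd3 (-0.80). Without IRP2 replicate 1 or control replicate 2 the count was 11, and without either other array 1.

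In liver, 9 genes were called, 4 of them IRE mRNAs. Tfrc stood at 2.78 ± 0.28 (SE, n = 2 per reaction), Alas2 at 2.13 ± 0.26, Slc11a2 at 2.12 ± 0.28 and Slc40a1 at 1.91 ± 0.25 on its less bright probe set. The others were Gstm6 at 2.62, Cxcl16 at 2.49, Lrpap1 at 2.27, Nt5c at 2.17 and Hmces at 1.41, the last with an adjusted p of 0.0279. On brightest probe sets 3 IRE mRNAs were called, and 5 when adjusted over the list alone. Fth1 had 0.71 ± 0.21 and Epas1 0.61 ± 0.31, both with an adjusted p of 1.0. The list was higher as a whole (camera, adjusted p = 2.79e-44, or 2.4e-05 with an estimated correlation). In total, 10 probe sets were higher and 0 lower by limma, with 239 and 97 at an unadjusted p under 0.05. The replicate block gave 62 higher and 4 lower, and those 4, named after their values were seen, were Gpr146 (-1.27), Marveld1 (-1.11), Synm (-1.07) and Tcn2 (-0.82). Without IRP2 replicate 1 or control replicate 2 the count was 2, and without either other array 4.

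In spleen, Tfrc reached 4.09 ± 0.43 (SE, n = 2 per reaction), a fold of 17.0, and Cxcl16 reached 3.37 ± 0.27. Ralgapa1 followed at 2.66 ± 0.24, Lrpap1 at 2.54, Nt5c at 2.22, Slc40a1 at 2.19 ± 0.25 on its less bright probe set, Ino80d, a subunit of the INO80 chromatin remodelling complex, at 2.17, Alas2 at 2.07 ± 0.26, Hmces at 1.73 and Shisa2 at 1.66. Their adjusted p-values ran from 2.72e-05 to 0.0355. The brightest probe set had -0.02 for Lrpap1, -0.02 for Ino80d and 0.39 for Ralgapa1. Alas2 was the 1 IRE mRNA called on its brightest probe set, and 5 were called when adjusted over the list alone. Fth1 (1.19 ± 0.21, adjusted p = 0.051), Tfrc (1.46 ± 0.28, adjusted p = 0.0934), Slc11a2 (1.39 ± 0.28, adjusted p = 0.117) and Epas1 (1.13 ± 0.31, adjusted p = 0.971) were called with the replicate block, at adjusted p-values of 0.00769, 0.00451, 0.0205 and 0.0153. The list was higher as a whole (camera, adjusted p = 1.22e-53, or 2.1e-05 with an estimated correlation). Altogether 19 probe sets of 14 genes were higher and 0 lower by limma, with 262 and 26 at an unadjusted p under 0.05. With the replicate block 88 were higher and 4 lower, and those 4, named after their values were seen, were Marveld1 (-1.09), Blmh (-0.91), Htra3 (-0.91) and Txndc17 (-0.90). The count was 9 without IRP2 replicate 2, 6 without control replicate 1 and 5 without either other array.

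In bone marrow, 3 probe sets were higher, those of Tfrc at 3.05 ± 0.43, Cxcl16 at 1.90 ± 0.27 and Ralgapa1 at 1.66 ± 0.24 (SE, n = 2 per reaction), each with an adjusted p of 0.0495, while the brighter Ralgapa1 probe set had -0.35. No IRE mRNA was called on its brightest probe set. Slc11a2 had 1.20 ± 0.28, Alas2 0.94 ± 0.26, Tfrc 0.92 ± 0.28 and Fth1 0.61 ± 0.21, while Epas1 had -0.72 ± 0.31. Adjusted over the list alone, 4 of these probe sets were higher and 1 lower. The other Epas1 probe set had 0.10, and the other Fth1 probe set 1.71 (adjusted p = 0.148, or 0.0116 with the replicate block). Slc11a2 and Alas2 were called with the replicate block (adjusted p = 0.0442 and 0.0489). For the IRE mRNAs list, bone marrow gave an increase at an adjusted p of 6.2e-05, but not with an estimated correlation (adjusted p = 0.0668) or without IRP2 replicate 2 (adjusted p = 0.0642). Of probe sets lower with IRP2, limma called 0, against 1439 at an unadjusted p under 0.05 (523 higher). A block for replicate number gave 114 higher and 105 lower, the lowest being Polb, which encodes DNA polymerase β, at -1.60 and Eif2b5, a subunit of a translation initiation factor, at -1.51. One array stood apart: control replicate 1 had a mean Spearman correlation with the spleen arrays of 0.908, against 0.824 to 0.825 for the other 3 bone marrow arrays, and the log2 ratios of the pairs correlated at 0.0178 across probe sets, against 0.187 to 0.364 in the other tissues. The count of higher probe sets was 0 without either IRP2 array (limma, 480 and 685 at an unadjusted p under 0.05) and 89 without control replicate 2, where 1679 were lower. Without control replicate 1 or IRP2 replicate 2, 1 probe set was lower.

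In brain, Kcnf1 had the highest ratio among probe sets with 1 gene symbol, at 3.13 ± 0.34 (SE, n = 2 per reaction), followed by Tfrc at 3.08 ± 0.43 and Dlg2, a scaffold protein of the postsynaptic density, at 2.95 ± 0.34. The control level of Kcnf1 was 8.07, but those of Dlg2 (3.54) and of the Slc40a1 probe set named here (4.76) lay below the 10th percentile of the tested probe sets (4.86), so the sizes and ranks of these 2 ratios are uncertain. The brightest probe sets of Kcnf1 and Dlg2 had 0.02 and -0.11. Alas2 and Arfip2 both stood at 2.31, with SEs of 0.26 and 0.23. Lrpap1 (2.25), Ankrd29 (2.02), Nt5c (1.83), Slc40a1 (1.67) and Prkg1, a cGMP-dependent protein kinase (1.64), completed the 10 highest named genes, with adjusted p-values from 0.00113 for Arfip2 to 0.035. Grm5, a metabotropic glutamate receptor, was the only probe set lower, at -1.40 ± 0.20 (adjusted p = 0.00877), and it was called without IRP2 replicate 2 but not without any 1 of the other 3 brain arrays, where the count lower was 0 by limma against 47 at an unadjusted p under 0.05 with all arrays. Of the IRE mRNAs, Tfrc (2.36 ± 0.28) and Alas2 were called on their brightest probe sets, and 5 were called when adjusted over the list alone. Slc11a2 had 0.74 ± 0.28 and the brightest Slc40a1 probe set 1.03 ± 0.28, each with an adjusted p of 1.0. The list was higher as a whole (camera, adjusted p = 3.94e-52, or 2.1e-05 with an estimated correlation). In total, 18 probe sets were higher, belonging to 13 genes apart from 3 without a single symbol, and a pair of these 3 stood above Kcnf1. A block for replicate number gave 42 higher. The brain pairs were far apart: Spearman correlations were 0.988 and 0.992 within replicates 1 and 2 and 0.901 to 0.909 between them. Without control replicate 1 the count was 6.

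**Figure D2:**
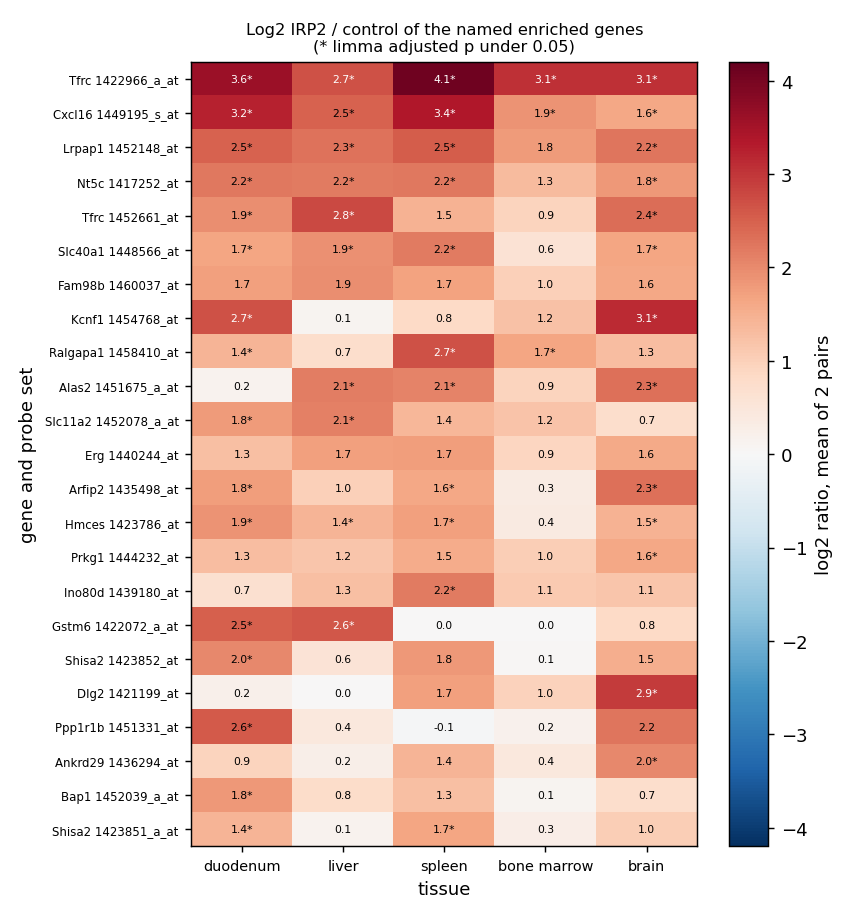
Log2 ratio of the IRP2 reaction to the control reaction, as the mean of 2 pairs (colour and printed value), for the named enriched probe sets (vertical axis) in each tissue (horizontal axis); an asterisk marks a limma adjusted p under 0.05. Tfrc and Cxcl16 each had a probe set called in all 5 tissues. Gstm6 was called in duodenum and liver and stood at 0.02 in spleen and 0.03 in bone marrow. Its control levels in spleen (4.17) and bone marrow (4.57) lay below the 10th percentile of the tested probe sets (4.55 and 4.64). Those ratios near 0 thus say little about binding.

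Many probe sets were called in more than 1 tissue. Tfrc and Cxcl16 each had a probe set called in all 5 tissues, and Hmces, Lrpap1, Nt5c and Slc40a1 each had one called in 4, while 17 of the called probe sets were called in a single tissue. The replicate block gave 10 probe sets in all 5 tissues, of Cxcl16, Fam98b, Lrpap1, Nt5c, Taf10 and Tfrc, and 154 in a single tissue. Duodenum and spleen shared 12 calls, against 0.0139 for independent lists of their sizes, liver and brain shared 8 (0.00597 for independent lists), and the 3 bone marrow calls were among those of duodenum and of spleen. These overlaps were 50, 26, 19 and 25 with the replicate block. Each tissue had its own control arrays, so these comparisons share no control. They do share 1 fit, with 1 pooled spread per probe set. A probe set with a small spread is thus favoured in every tissue, which the numbers for independent lists leave out. Regardless of any threshold, 69 probe sets of 46 genes had both IRP2 arrays above both controls in all 5 tissues and 6 had both below. Chance gives 3.88 each way if the 4 arrays of a tissue are exchangeable, and 0.601 if IRP2 and control are exchangeable only within a replicate pair.

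The ratio differed between tissues for 1 of the probe sets of Cxcl16. On that probe set it was 2.84 in spleen, 1.98 in duodenum, 1.22 in liver, 0.51 in brain and -0.01 in bone marrow (limma F test of equal ratios, adjusted p = 0.0302, n = 2 per group). The other Cxcl16 probe set, called in all 5 tissues, had 3.37, 3.23, 2.49, 1.61 and 1.90 in the same order and an adjusted p of 1.0 in that test, or 0.0486 with the replicate block; its control level in brain, 4.71, lay below the 10th percentile of the tested probe sets (4.86), so the size of its brain ratio is uncertain. No other probe set was called by this test. Without any 1 of 16 arrays the count was 0 by limma, with 111 to 1842 probe sets at an unadjusted p under 0.05: all arrays of duodenum, liver and spleen, both IRP2 arrays and control replicate 2 of bone marrow, and control replicate 1 of brain. It was 2 without either IRP2 array of brain. The following genes by p were Gstm6 (adjusted p = 0.122), Kcnf1 and Alas2 (both 0.523) and Dlg2 (0.654). At an unadjusted p under 0.05 there were 182 probe sets, where chance gives 1508, and 1921 with the replicate block. A count that far below chance shows that the F test without the block was too conservative. A probe set not called by it may still differ between tissues. With the replicate block 12 probe sets were called, 11 of them belonging to 10 named genes. Among these Gstm6 ranged from 2.62 in liver to 0.02 in spleen, Ppp1r1b from 2.58 in duodenum to -0.05 in spleen, Dlg2 from 2.95 in brain to 0.02 in liver, and Alas2 from 2.31 in brain to 0.15 in duodenum. The control levels of Gstm6 in spleen (4.17) and Dlg2 in liver (2.84) lay below the 10th percentile of the tested probe sets (4.55 and 4.82), so a ratio near 0 there says little about binding.

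Probe sets of 1 gene often gave different ratios. For Slc40a1 the brighter probe set had a mean of 0.45 over the tissues and the dimmer 1.61. For Tfrc in spleen, the probe set of middle brightness had 4.09 and the brightest 1.46, while in liver they had 2.68 and 2.78. Slc11a2, which is known to make transcripts with and without an IRE in the 3' untranslated region, had means over tissues of 1.45, -0.10, 0.63 and 0.28 on its 4 probe sets from the brightest to the dimmest. Fth1 stood at 0.83 and 1.13 on its 2 probe sets, both called on the mean over tissues. Outside the IRE mRNAs, the 4 probe sets of Lrpap1 had 2.26, 1.47, -0.02 and -0.06, and the brightest and the enriched probe set had 0.10 and 1.17 for Dlg2, 0.02 and 1.27 for Ino80d and 0.05 and 1.59 for Kcnf1. Control levels of the enriched Dlg2 probe set (2.84 to 3.82) lay below the 10th percentile of the tested probe sets in every tissue. Those of the enriched Kcnf1 probe set did in every tissue but brain. The sizes of these mean ratios are therefore uncertain.

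**Figure D3:**
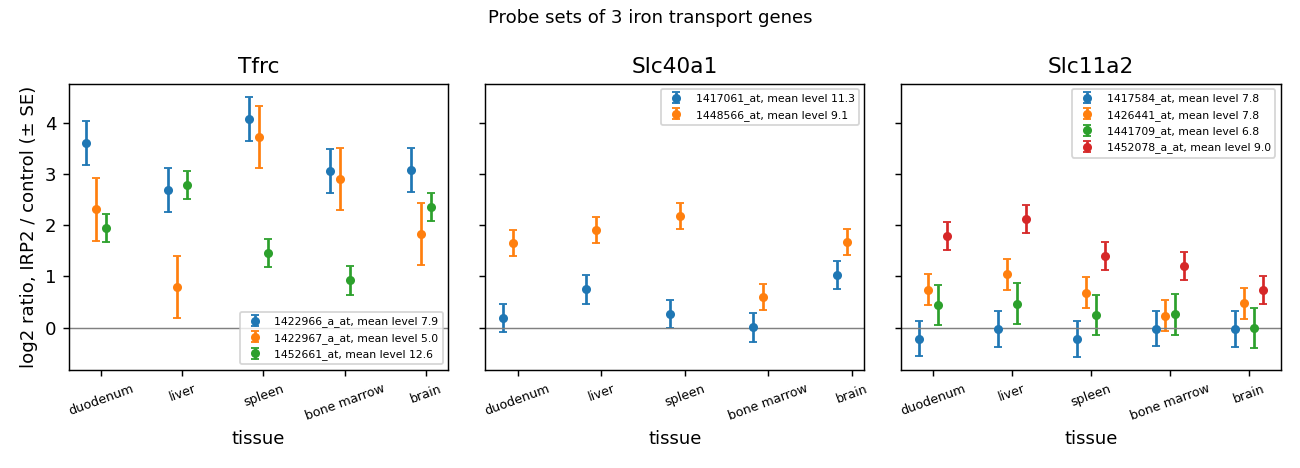
Log2 ratio of the IRP2 reaction to the control reaction (vertical axis, points are fitted values and bars ± SE from limma) by tissue (horizontal axis) for each probe set of Tfrc, Slc40a1 and Slc11a2; the legends give each probe set's mean log2 level. In Slc40a1 the dimmer probe set lies above the brighter one in every tissue, at 2.19 against 0.26 in spleen, and in Slc11a2 the brightest of 4 probe sets has the highest ratio in every tissue.

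A second list held 14 mRNAs named elsewhere as bound by an IRP. Some of them were reported from these arrays, so the list is not independent evidence of its direction. Of the 12 measured, 4 were called on the mean over tissues, namely Egr2 (1.62), Cxcl16 (1.31), Slc49a4 (0.85) and Pfn2 (0.80), or 7 with the replicate block, which added Hao1 (0.72), Gyg (0.58) and Cep95 (0.57), and 8 when adjusted over the list alone, which is not independent evidence either. The list was higher on the mean (camera, adjusted p = 1.74e-23, or 0.000381 with an estimated correlation) and in each tissue except bone marrow (adjusted p = 0.67). The zinc finger gene Egr2 had ratios from 0.83 in bone marrow to 2.13 in duodenum, and limma called it in no single tissue; with the replicate block it was called in duodenum (adjusted p = 0.00192), liver (0.0272), spleen (0.00266) and brain (0.0241). Mitochondrial Ndufs1 and the amyloid precursor App, both on that list, had -0.03 and 0.01 on the mean over tissues.

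Genes of iron metabolism listed as without a canonical IRE were not called as a group. Their untranslated regions were not searched, so an IRE in some of them cannot be excluded. The 28 measured, among them that for hepcidin, had a median of -0.05 on the mean over tissues with 0 called by limma (adjusted p of the list 0.725). The 7 measured enzymes of heme synthesis other than Alas2 had a median of -0.09 (adjusted p = 0.446), which sets them apart from Alas2 at 1.52.

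Outside both lists of bound mRNAs, 3 list tests were called. Pancreas acinar markers, digestive enzymes whose median log2 level over genes was 11.8 in the duodenum controls and 6.37 in the liver controls, were higher in liver as a list, with positive ratios in 9 of 9 genes and a median of 0.24 (adjusted p = 0.0271). That call was lost with an estimated correlation (adjusted p = 0.988) and without any 1 of the 4 liver arrays, where the pancreas acinar markers list, liver, had adjusted p-values from 0.0642 without control replicate 1 to 0.118 without IRP2 replicate 1. In bone marrow the list of 16 citrate cycle enzymes was lower as a whole, with a median of -0.39 (adjusted p = 0.0186), and so was that of 8 erythroid markers, with a median of -0.46 (adjusted p = 0.0345). No member of either was called on its own, the lowest being Dld, a dehydrogenase subunit, at -1.48 and Car1, a carbonic anhydrase, at -0.68. Both calls were lost with an estimated correlation (adjusted p = 0.988 each), and the erythroid one with the replicate block (adjusted p = 0.0559). Bone marrow control replicate 1 stood above the mean of the other 3 bone marrow arrays by a median of 0.92 for the citrate cycle and 0.91 for the erythroid markers. The citrate cycle list, bone marrow, had an adjusted p of 0.934 without that array and 0.204 without IRP2 replicate 1, and the erythroid markers list, bone marrow, 0.858 and 0.679.

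Some lists were called in the fit with the replicate block and not in the fit without it. The lists of the respiratory chain and the cytosolic ribosomal proteins were lower as a whole in bone marrow (adjusted p = 0.0206 and 0.0134) and on the mean over tissues (adjusted p = 0.0474 and 0.0493). The list of liver markers was lower in duodenum (adjusted p = 0.028), that of duodenal epithelium markers higher in bone marrow (adjusted p = 0.0474) and that of pancreas acinar markers higher on the mean (adjusted p = 0.000265). With an estimated correlation and no block, each of these 7 list tests had an adjusted p of 0.988. Without the block and without bone marrow control replicate 1, the direction of both the respiratory chain and the ribosomal proteins was reversed: the respiratory chain list, bone marrow, had an adjusted p of 0.0511 and the cytosolic ribosomal proteins list, bone marrow, 0.0421, and on the mean they had 0.841 and 0.878. The other lists were called in none of the 6 comparisons in either fit. Their adjusted p-values without the block ran from 0.388 to 0.974 for replication-dependent histones (2 genes measured), 0.647 to 0.958 for immediate early genes, 0.34 to 0.892 for housekeeping genes of the cytoskeleton and glycolysis, 0.267 to 0.892 for spleen B and T cell markers, 0.41 to 0.892 for myeloid markers, 0.34 to 0.892 for brain markers and 0.238 to 0.892 for muscle markers. Each set of markers of a studied tissue had its highest median level over genes in the controls of that tissue, at 11.5 for duodenal epithelium, 13.1 for liver, 9.30 for spleen B and T cells, 11.4 for myeloid cells in bone marrow and 8.84 for brain.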

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

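The tests of bright and dim probe sets and of noise between probe sets were chosen only after the result was seen; the other tests of this part were planned.

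The ratio differed between tissues by limma's F test for Cxcl16 on 1 probe set (adjusted p = 0.0302), at 1.98 in duodenum, 1.22 in liver, 2.84 in spleen, -0.01 in bone marrow and 0.51 in brain. The other Cxcl16 probe set had an adjusted p of 1.0 in the same test and was called in each tissue, at 1.90 in bone marrow. With the replicate block the adjusted p was 0.0126 for the first and 0.0486 for the other. Also with the block, the adjusted p was 0.0126 for Ppp1r1b, 0.0151 for Kcnf1, Dlg2 and Gstm6, 0.0328 for Arfip2 and Alas2, 0.0424 for Shisa2, and 0.0486 for Grm5 and Ankrd29. Kcnf1 had 3.13 in brain and 0.10 in liver, Dlg2 2.95 in brain and 0.02 in liver, and Ppp1r1b 2.58 in duodenum and -0.05 in spleen. The control levels in liver were 3.20 for Kcnf1 and 2.84 for Dlg2, below the 10th percentile of the tested probe sets (4.82), so those ratios near 0 say little about binding, while that of Ppp1r1b in spleen was 5.97. Controls of Grm5 (2.30 to 2.82) and Ankrd29 (2.26 to 2.92) also lay below the 10th percentile of each tissue except brain. Those of Shisa2 did in liver (4.32), bone marrow (2.97) and brain (4.83), and those of Gstm6 in spleen (4.17), bone marrow (4.57) and brain (4.125). The differences of Grm5, Ankrd29, Shisa2 and Gstm6 between tissues are therefore uncertain as differences in binding. The brightest probe sets of Kcnf1 and Dlg2 were not called by this test with the block (adjusted p = 0.829 and 0.837). Assigning the 10 pairs to tissues in other ways gave as many probe sets in 1 of 100 assignments drawn from 945, the real one, with 12 probe sets against at most 2. Chance assignment is thus unlikely to give that count, but assignments that were not drawn could still reach it. Duodenum, liver and spleen share the diet, and there Alas2 had 0.15, 2.13 and 2.07 and Ppp1r1b 2.58, 0.44 and -0.05, in that order. Diet does not account for differences among tissues that share it. No test compared these tissues alone, however, and the F test without the block called neither gene. Between those tissues and bone marrow or brain, diet and age go with tissue and were not tested.

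A signal outside the tested probe sets came from the array's own control probe sets for the mouse transferrin receptor, which no comparison used. Their mean log2 ratios of IRP2 to control over the tissues were 2.16 for the 3' probe set, 1.43 for the middle one and 0.96 for the 5' one, with both IRP2 arrays above both controls in 5, 4 and 5 of the 5 tissues. The middle and 5' probe sets were dim, with mean control levels of 3.90 and 2.92, so the sizes of their ratios and the order from 3' to 5' are uncertain.

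The first pattern weighed is the excess of probe sets higher with IRP2. Of 100 splits of the arrays within tissues drawn from 3888, 38 gave at least the real 110, the highest other giving 5615, so this count alone does not exclude chance. The other 37 all divided brain by replicate number, a structure of the samples, and among the 63 splits that did not, the highest other gave 12. When every pair was parted and the block kept, 1 of 100 splits drawn from 512, the real one, reached 322. The highest other gave 307, in a split that kept the direction of 9 of the 10 pairs. Chance is thus unlikely to give that count, but splits that were not drawn could still reach it. Carry-over of the same RNA with the recombinant protein would add a similar excess in every tissue. The excess followed the control level of the tissue with a median Spearman rho of 0.7 (bootstrap interval 0.7 to 0.8 over the 110). Each rho rests on 5 tissues, and the probe sets share arrays, so the interval is too narrow. The rho was at least 0.5 for 78 of the 110 probe sets, which as a set goes against an equal excess in every tissue. A rho over 5 tissues cannot decide for a single probe set, and tissue differences shared by all probe sets were not removed. Carry-over stays open for single probe sets, above all for the 14 at or below 0.2. Binding by IRP2 and binding to the beads or antibody in the presence of any protein stay open, since no reaction with another protein was compared.

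The second pattern is that probe sets of 1 gene gave different ratios. If chance between probe sets made the difference, the larger ratio would change places between replicates. Comparing the 2 brightest probe sets of each gene, 39 of 47 genes kept it on the same one (exact p = 5.54e-06). These genes were chosen by calls that used both replicates, which favours agreement, so that p is not independent evidence. Of 30 genes chosen from replicate 1 alone, 27 kept it on the same one (exact p = 8.43e-06), which argues against chance. If bright probe sets were compressed, the brightest would have a smaller ratio than the next brightest in most genes, and it did in 25 of 47 (exact p = 0.771), which leaves a part for compression open. Transcripts with and without an IRE, as Slc11a2 makes, may also give such differences and were not tested.

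The third pattern is bone marrow control replicate 1, which correlated more with spleen (0.908) than the other 3 bone marrow arrays did (0.824 to 0.825). Spleen RNA in that control would raise spleen B and T cell markers above other probe sets of their level. Their median difference from the other 3 arrays, 0.39, lay at percentile 32.7 of 10000 level-matched random lists, with 8 of 11 higher. The list cannot decide, because Cd8a (10.3 on the other 3 arrays, 8.64 in the spleen controls), Cd3e (7.67 and 7.37) and Cd4 (7.73 and 7.66) were not brighter in spleen. Of markers brighter in spleen, Cd52 had a difference of 1.23, Ms4a1 0.75 and Cd22 0.45, but Cr2 had -0.001 (levels 5.91 and 10.1). Bone marrow also expresses markers of this list, 9 of 11 above the array median. The other explanation, a narrower signal range on the other 3 arrays, cannot be told apart from a difference in the RNA: bright myeloid markers lay at percentile 100, a median difference of 1.22 against 0.98 at the upper bound of the random lists' interval, while the bound written beforehand covered only values below the random lists. The citrate cycle also lay above (percentile 99.7), and the dim liver and brain markers below (0.44 and 0.93), so level alone does not account for these lists, and a narrower range may still be part. No biological explanation was tested. The labels give bone marrow RNA for all 4 reactions, and a difference between RNA pools was not examined.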

How the results depend on the processing

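The fits that leave out bone marrow, or bone marrow and brain, were chosen only after the result was seen; the other settings were planned.

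Of 146 results for named genes, 65 were called. Over the settings these 65 gave 857 gene and setting results, of which all kept their direction and 730 stayed past the threshold. None of the 65 was lost with the replicate block. The rule for the highest and lowest genes asked for both IRP2 arrays on the same side of both controls. Leaving out 1 array therefore could not reverse those genes, and their kept direction there is no evidence. Over all named genes, settings other than left-out arrays gave 674 results on the same side of the threshold, 42 newly past it, 13 no longer past it and 1 reversed; left-out arrays gave 828, 14, 114 and 12. For lists the numbers were 85, 12, 8 and 0, and with left-out arrays 129, 22, 8 and 5. Quantile normalization and median centring moved no median log ratio by over 0.1. Causes were not tested except where stated.

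With the replicate block the counts of higher probe sets were 85 in duodenum, 62 in liver, 88 in spleen, 114 in bone marrow, 42 in brain and 322 on the mean, and 12 for the tissue difference. It took away no call of a named gene. Of the list tests it took away the call of erythroid markers in bone marrow, added the 7 given in the report and changed no other call. With the block and bone marrow left out, the counts were 367, 232, 236 and 96 in duodenum, liver, spleen and brain and 686 on the mean.

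In bone marrow, against 3, quantile normalization gave 14, and no filter, median centring, array weights, an adjusted p under 0.01 and a fit of the tissue alone gave 0. For the tissue difference, against 1, array weights gave 3, and quantile normalization, median centring, an adjusted p under 0.01 and leaving out bone marrow gave 0. Array weights gave 45 in duodenum, 93 in liver, 205 in spleen and 0 in brain. An adjusted p under 0.01 gave 9 in duodenum and 9 in brain, a stricter threshold by construction, and the 2-fold minimum 51 on the mean. Fits of each tissue alone, which have fewer arrays, gave 0 in duodenum, 193 in spleen and 0 in brain. Tissues as replicates gave 210 on the mean. Leaving out bone marrow and brain gave 63 in duodenum, 48 in liver and 73 in spleen. For the counts of 0, limma's counts at an unadjusted p under 0.05 were 132 to 1195 in bone marrow, 404 in duodenum, 56 and 58 in brain, and 111 to 1842 for the tissue difference. For the IRE mRNAs list, bone marrow had an adjusted p of 0.0668 with an estimated correlation, and 1.2e-06 (without IRP2 replicate 1) to 0.0642 (without IRP2 replicate 2) with left-out arrays. The list tests called, 14, were 19 with no filter, 12 with quantile normalization, 20 with the block, 10 with an estimated correlation and 17 with the mean of probe sets.

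Leaving out each array in turn leaves 1 array in a group, which is assumed to vary like the other groups. Counts ran from 1 (control replicate 1 or IRP2 replicate 2) to 11 in duodenum, 2 (IRP2 replicate 1 or control replicate 2) to 4 in liver, 5 (IRP2 replicate 1 or control replicate 2) to 9 in spleen, 0 (either IRP2 array) to 89 (control replicate 2) in bone marrow, 6 (control replicate 1) to 15 in brain, 88 (spleen control replicate 1) to 139 (bone marrow control replicate 1) on the mean, 0 to 2 for the tissue difference, and 13 (liver IRP2 replicate 1) to 26 (bone marrow control replicate 2) list tests.

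Reversed log2 ratios were of uncalled results. The brightest Slc40a1 probe set in bone marrow, 0.00, had -0.044 with median centring and -0.47 (without control replicate 2) to 0.47 (without control replicate 1) with left-out arrays, and in duodenum -0.053 (without control replicate 1) to 0.44 (without control replicate 2). Alas2 in duodenum ran from -0.053 (without control replicate 2) to 0.35 (without control replicate 1), Clps in spleen from -0.59 (without control replicate 1) to 0.28 (without control replicate 2) and Lcn2 on the mean from -0.49 (without brain control replicate 1) to 0.042 (without brain control replicate 2). In bone marrow, without control replicate 2 to without control replicate 1, Cdc14a ran from -0.96 to 0.074, Sdhd from -1.42 to 0.11, Idh3a from -1.29 to 0.0078 and Fh1 from -0.98 to 0.0015.

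List directions reversed without bone marrow control replicate 1. The citrate cycle list, bone marrow, ran from 0.00165 (without control replicate 2) to 0.934 (without control replicate 1). The respiratory chain list, bone marrow, ran from 6.8e-05 to 0.785, reversed at 0.0511, and the cytosolic ribosomal proteins list, bone marrow, from 7.6e-06 to 0.65, reversed at 0.0421. The respiratory chain list, all tissues, ran from 0.000903 to 0.93, reversed at 0.841, and the cytosolic ribosomal proteins list, all tissues, from 6.8e-05 to 0.901, reversed at 0.878.

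The offset for linear values and the IRE motif search were not run. Probe sets dimmer than the array median on nearly all arrays were not tested, which limits what is said of weakly expressed mRNAs.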

Other observations

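Apart from Hao1 and Gyg, members of the second list, the results of this part were chosen only after their values were seen. Some mRNAs were called in single tissues only when replicate number was a block. Fam98b, a subunit of the tRNA ligase complex and already among the named genes on the mean, had 1.73 in duodenum, 1.95 in liver, 1.69 in spleen, 1.00 in bone marrow and 1.64 in brain, with adjusted p-values by limma from 0.000999 in liver to 0.049 in bone marrow. Taf10, a subunit of the transcription factor TFIID, had 1.62, 1.45, 1.49, 0.99 and 1.42 on its more enriched probe set (adjusted p from 0.000765 to 0.0381) and 0.24 on the mean over tissues on the other. Chmp2b, a component of the ESCRT machinery, had 1.67 in duodenum, 1.24 in liver, 1.41 in spleen and 1.19 in brain, and Csf2rb, a cytokine receptor subunit, folds of 3.51 in duodenum, 3.26 in liver and 2.82 in spleen (adjusted p = 0.00156, 0.00365 and 0.00649) on 1 of its 2 probe sets, the other having 0.33 on the mean over tissues. Hao1, an oxidase of liver peroxisomes, was called among the tissues in liver alone, at a fold of 2.83 (adjusted p = 0.0473), and Gyg, which primes glycogen synthesis, in spleen at 1.09 (adjusted p = 0.00971). The control level of Hao1 was 11.5 in liver. In each other tissue it was 3.70 to 4.55, below the 10th percentile of the tested probe sets, so the lack of a call there says little about binding. Without the block, limma called none of the mRNAs of this paragraph in a single tissue.

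Of mRNAs lower in the IRP2 reaction with the block, Txndc17 had -0.67 on the mean over tissues (adjusted p = 0.000241) on 1 of its 3 probe sets, and -0.18 and -0.19 on the others. Ptpro, a receptor phosphatase, had -0.50 (adjusted p = 0.0201). The pancreatic carboxypeptidase Cpb1 was higher in spleen with the block, at 1.35 (adjusted p = 0.00275), but only 2 of 9 pancreas acinar genes had positive ratios there, with a median of -0.03. Pancreas acinar markers had median log2 levels over genes of 11.8 in the duodenum controls and 8.69 in the spleen controls, against 6.37 in liver, 5.58 in bone marrow and 5.59 in brain.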
